A study of Homo sapiens with 13 samples.

How the data were processed

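ChIP-seq libraries of MDA-MB-231 cells were made from sonicated, cross-linked chromatin with antibodies to YAP, TAZ, TEAD4 and JUN, 2 replicates each, and with control IgG (2 rabbit, 3 mouse libraries), per the labels. Samples were grouped by the factor named in their titles. Per the submitters' processing notes, CASAVA, Bowtie 0.12.7, SAMtools and MACS2 2.0.10 were used with build hg19. Per the labels, the authors called peaks within the IDR (irreproducible discovery rate) framework, which ranks peaks by how well they recur between replicates. YAP and TAZ were called against the pooled rabbit IgG libraries 1 and 2, TEAD4 against mouse IgG 3 and 4, and JUN against mouse IgG 3 and 5. The labels carry an IDR value of 0.01; other filters are not given in the sources used here.

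There is 1 deposited list per factor, named in the labels of both replicates, with no values per replicate. Each deposited peak has a start, an end and a summit, the fold enrichment over the IgG control (a ratio), and the −log10 of its p-value; the q-values were not used here. The deposited score was 10 times the −log10 p-value, to within 1, at 100% of peaks and was not used further. Enrichment and p are the authors' own values per peak and were used only to rank, divide or describe peaks within a list; correlations between lists use ranks across sites. Read depth is unknown here, so no precision from depth can be given. The replicates are described by the submitters as independent, but the lists carry no spread between them.

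The names of the raw files in the labels place the YAP, TAZ and rabbit IgG libraries on 1 sequencing run, the TEAD4 libraries, JUN replicate 1 and mouse IgG 3 and 4 on another, and JUN replicate 2 and mouse IgG 5 on the last of 3. YAP with TAZ, and TEAD4 with part of JUN, are therefore compared within a run. YAP and TAZ against TEAD4 and JUN differ in run and in IgG, and these cannot be separated from the factor. Peak names in the TAZ list carry a tag naming both YAP and TAZ. Names in the JUN list carry another replicate tag than those of the other lists. What these tags mean, and so which libraries the JUN list was made from beyond what the labels say, is not given in the sources used here. Peak numbers in the names ascend along each chromosome and run up to 35378 for YAP, 43671 for TAZ, 28115 for TEAD4 and 96825 for JUN. Gaps between them were read as unlisted candidate peaks, which assumes that the numbers count all candidates.

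Peaks were counted as shared when they overlapped by at least 1 bp. Chance overlap was the mean over 1000 draws in which a list was moved along each chromosome by a random offset, wrapping at the ends of the span covered by all 4 lists. This keeps the number, width and spacing of peaks. Empirical p-values are one-sided. Overlapping peaks of all lists were merged into regions, and each region was assigned to 1 of 15 classes by the factors it held. Shares have Clopper-Pearson 95% intervals. JUN presence was tested by two-sided Fisher exact tests with Woolf intervals for the odds ratio, which take regions as independent although regions can cluster. Of these 3 tests, that on regions with YAP or TAZ was not in the design fixed in advance; it was added once the lists had been examined, before any test of JUN presence was run. Summit distances take the nearest overlapping peak, and their intervals and those of Spearman's rho come from 1000 resamples of chromosomes. Peak strength was compared by two-sided permutation tests of the rank sum with 100000 resamples. Benjamini-Hochberg adjustment was applied within each family (12 overlaps, 3 Fisher tests, 12 strength tests). The threshold was 0.05.

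Regions named in the text follow a rule fixed before the data were examined: the 10 regions of all 4 factors with the best mean rank of enrichment, the 100-kb windows with the most such regions, and the most enriched peak of each list. The rule first named genes, and falls back to positions where no hg19 annotation is used. Other sites named, on chromosome 6, were chosen after their values were seen.

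Alternatives were a reciprocal overlap of 50%, summits within 200 bp, the stronger 50% of each list, lists of equal length (7709 peaks), peaks narrowed to 200 bp around the summit, random local shifts of 5 to 50 kb as the chance model, chromosomes left out in turn, −log10 p in place of enrichment, narrow peaks only, and 3 equal parts by YAP enrichment. Peaks narrowed to 200 bp in the Fisher tests were added once the lists had been examined, before any test of JUN presence was run. The 3 equal parts by TEAD4 enrichment, and leaving out 15 bins of 1 Mb that each hold at least 3 strong TAZ and TEAD4 regions without YAP, or those regions themselves, were added after the results had been seen.

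Distances to transcription start sites, DNA motifs and the 13 gene lists fixed in advance were not analysed here. The gene table used here is on GRCh38.p14 and the peaks are on hg19, no genome sequence was used, and positions were not converted between builds.

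The overlap code was tested on simulated data: a list of the size of the YAP list (7709 peaks), placed to share 20% or 60% of YAP peaks, gave 20.2% and 60.1%, and an unrelated list gave 0.285% against a chance value of 0.338%. Overlap counts were also checked against bedtools 2.31.1. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.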

Results

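The study mapped where 4 transcriptional regulators sit on the genome of MDA-MB-231, a human breast cancer cell line, by chromatin immunoprecipitation and sequencing (ChIP-seq). YAP and its paralogue TAZ (encoded by WWTR1) are the coactivators at the end of the Hippo pathway and bind DNA through partner proteins. TEAD4 is a DNA-binding partner of both, and JUN is a subunit of the AP-1 transcription factor. The series holds 13 libraries: 2 replicates for each of the 4 factors, 2 rabbit IgG controls and 3 mouse IgG controls. One peak list per factor was analysed, named in the labels of both replicates of that factor, so the values below have no replicate spread and the read depth of the libraries is unknown here. Intervals are exact binomial (Clopper-Pearson) 95% intervals unless stated otherwise, and they cover counting error only. All positions are on hg19, and no gene annotation of that build was used here, so regions are named by position.

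The YAP list held 7709 peaks, the TAZ list 9798, the TEAD4 list 8406 and the JUN list 24554. Peaks had a median width of 554 bp for YAP, 587 bp for TAZ, 503.5 bp for TEAD4 and 730 bp for JUN. Together the peaks of each list covered 4.64 Mb for YAP, 6.33 Mb for TAZ, 4.60 Mb for TEAD4 and 20.6 Mb for JUN. The fold enrichment over IgG given by the authors for each peak had a median of 7.35 for YAP, 6.96 for TAZ, 7.20 for TEAD4 and 11.7 for JUN. The weakest peak listed had a −log10 p of 24.3 for YAP, 22.0 for TAZ and 24.7 for TEAD4, against 54.4 for JUN. The most enriched YAP peak lay on chromosome 1 (19378928 to 19379518, 38.2-fold), that of TAZ on chromosome 4 (165125408 to 165126098, 35.8-fold) and that of TEAD4 on chromosome 18 (71983878 to 71984621, 33.0-fold). Each of these overlapped peaks of all other lists. The most enriched JUN peak, on chromosome 7 (98047724 to 98048749, 39.9-fold), overlapped no peak of the other 3 lists.

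The first comparison asked how far the 4 factors occupy the same sites. YAP and TAZ shared most of their sites: 92.4% of YAP peaks (91.8 to 93.0) overlapped a TAZ peak by at least 1 bp, and 72.5% of TAZ peaks (71.6 to 73.4) overlapped a YAP peak. TEAD4 was present at 74.6% of YAP peaks and 67.0% of TAZ peaks, and in turn 68.7% of TEAD4 peaks held YAP and 78.8% held TAZ. JUN was present at 77.0% of YAP peaks (76.0 to 77.9), 74.7% of TAZ peaks and 68.3% of TEAD4 peaks. In the other direction the shares were lower, with YAP at 23.9% of JUN peaks, TAZ at 29.5% and TEAD4 at 23.1%.

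Lists moved to random positions along each chromosome overlapped far less. Such shifts take no account of which parts of the genome can be bound in these cells. Overlap above them does not tell whether these factors share sites more than other factors bound in the same cells would. The mean over 1000 circular shifts was 0.432% for YAP peaks with TAZ, 0.350% for YAP with TEAD4 and 1.27% for YAP with JUN. In all 12 directed comparisons no shifted list reached the observed overlap (one-sided permutation p from the shifts = 0.000999, the smallest that 1000 shifts can give; Benjamini-Hochberg adjusted p = 0.000999). The shares with JUN moved with list length: with each list reduced to its 7709 strongest peaks, which shortens the JUN, TAZ and TEAD4 lists, JUN was present at 41.4% of YAP, 41.9% of TAZ and 34.5% of TEAD4 peaks, and YAP at 40.6% of JUN peaks. YAP and TAZ were called against the same IgG libraries and the peak names in the TAZ list carry a tag naming both proteins, so how independent these lists are is not settled by the sources used here.

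**Figure D1:**
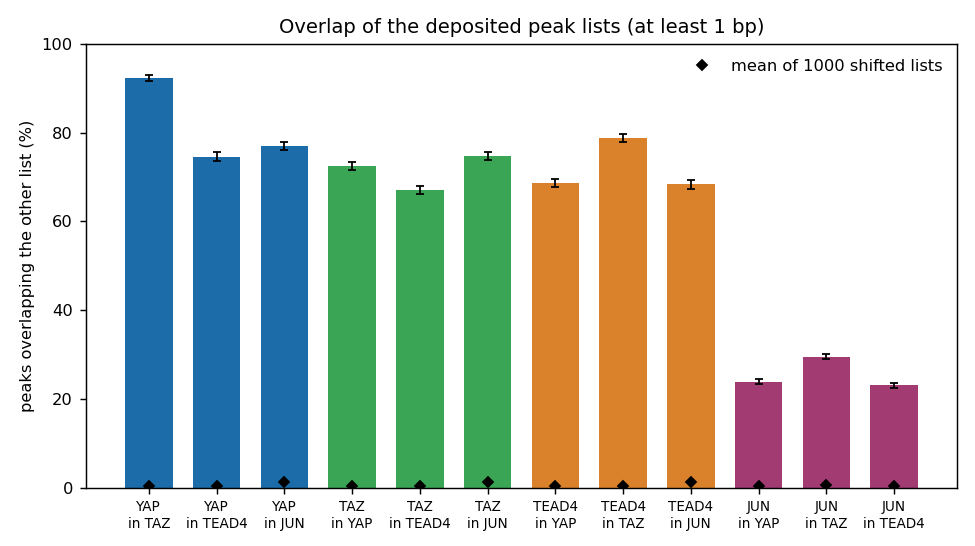
Share of the peaks of each list (bars, in %, with 95% Clopper-Pearson intervals) that overlap a peak of a second list by at least 1 bp, and the mean share over 1000 circular shifts of a list (diamonds). The bars run from 23.1% for JUN peaks in the TEAD4 list to 92.4% for YAP peaks in the TAZ list, and the diamonds lie at 1.31% or below.

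Overlap followed peak strength. With each list ordered by p and divided into 10 equal parts, TAZ was present at 770 of the 771 peaks (99.9%) of the strongest YAP part and 69.1% of the weakest (65.7 to 72.3). TEAD4 was present at 99.5% of the strongest and 42.1% of the weakest YAP part. The share of YAP peaks with JUN changed less, from 82.4% to 68.2%. Among JUN peaks, 62.5% of the strongest part (60.5 to 64.4) and 15.9% of the weakest held any of the other 3 factors. TAZ and TEAD4 peaks departed from this order. YAP was present at 82.4% of the strongest TAZ part (79.9 to 84.8). It was present at 96.3%, 97.7% and 97.2% of parts 2, 3 and 4, 92.5% of part 5 (90.7 to 94.1) and 25.9% of the weakest. JUN was present at 70.6% of the strongest TAZ part and 81.8% of part 3. In the TEAD4 list, YAP was present at 82.3% of the strongest part and 93.9% of the next, and JUN at 68.4% and 76.5%.

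**Figure D2:**
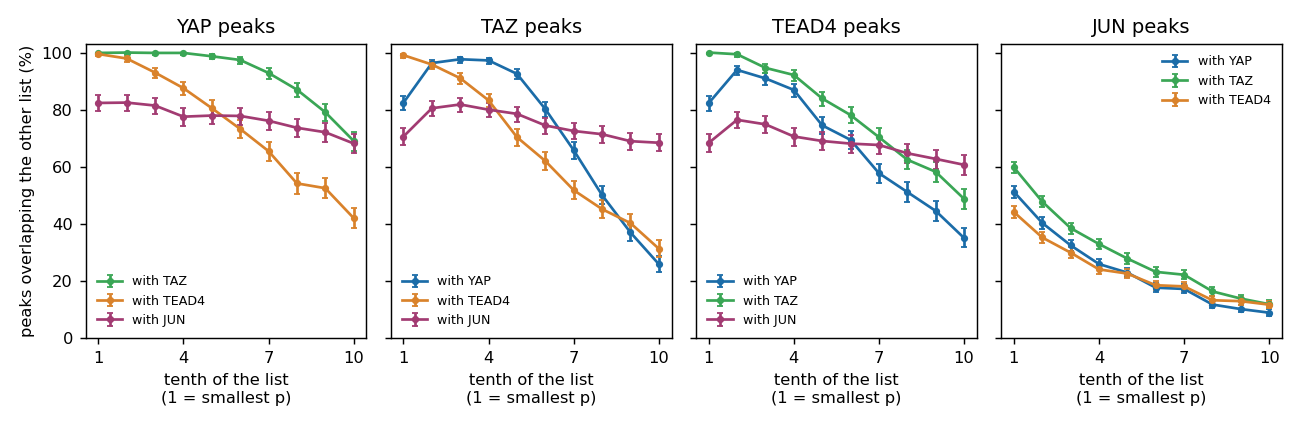
Share of peaks that overlap each other list (y axis, in %, with 95% Clopper-Pearson intervals) against the part of the list by p (x axis, 10 equal parts, 1 for the smallest p), in 1 panel per list. TEAD4 at YAP peaks falls from 99.5% to 42.1%, and JUN at YAP peaks only from 82.4% to 68.2%. YAP at TAZ peaks is lower in part 1 (82.4%) than in part 3 (97.7%) or part 5 (92.5%).

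Some of the strongest TAZ and TEAD4 peaks lacked YAP. Of the 1960 TAZ peaks in the top 20% by p, 208 (10.6%, 9.28 to 12.1) lacked YAP, as did 200 of the 1682 TEAD4 peaks in the top 20% (11.9%). TEAD4 was present at 194 of these 208 TAZ peaks (93.3%, 89.0 to 96.3) and at 97.9% (97.2 to 98.6) of the 1752 with YAP. In the reverse direction, 1 of the 1543 YAP peaks in the top 20% lacked TAZ. JUN was present at 8.17% (4.83 to 12.8) of the 208 peaks without YAP and at 83.6% (81.7 to 85.3) of the 1752 with YAP (odds ratio 0.0175, 95% Woolf interval 0.0105 to 0.0292; two-sided Fisher exact p = 2.12e-109). The peaks without YAP were wider, with a median of 938 bp against 751 bp, and less enriched, with a median of 8.43-fold against 12.8-fold, but had the higher median −log10 p, 156 against 113. Chromosome 6 between 26 and 29 Mb held 73 (37.6%) of the 194 merged regions of this kind. Of the 194, 124 lay in 15 bins of 1 Mb with at least 3 each. These bins include those of the chromosome 6 interval (31, 27 and 15 regions), and the remaining bins lay on other chromosomes. The densest bins elsewhere were on chromosome 5 (180000001 to 181000000, 7 regions) and chromosome 16 (3000001 to 4000000, 6 regions). In that interval the TAZ list had 95 peaks, or 31.7 per Mb against 4.15 over chromosome 6, and the TEAD4 list 98, or 32.7 against 3.92. The YAP list had 8 (2.67 against 3.04 per Mb) and the JUN list 24 (8.00 against 9.11), close to their density over the chromosome. If the numbers in the peak names count all candidates, at most 55 YAP and 138 JUN candidates there were not listed. The top 20%, this set of sites and the interval were chosen after the overlaps had been seen. The Fisher test takes peaks as independent, and these sites cluster, so its p-value and interval overstate the precision.

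The second comparison asked which combinations of factors occur together. Merging all overlapping peaks gave 28100 regions. JUN alone accounted for 16291 of them (58.0%), and 4284 (15.2%) held all 4 factors. The next largest classes were YAP with TAZ and JUN (1248 regions), YAP with TAZ and TEAD4 (1209), TAZ with JUN (1119) and TEAD4 alone (855). YAP alone was found at 153 regions and TAZ alone at 486. Of the 7048 regions with both YAP and TAZ, 77.9% (77.0 to 78.9) also held TEAD4, 78.5% (77.5 to 79.4) held JUN and 60.8% (59.6 to 61.9) held both. The corresponding means over 1000 shifts were 0.450%, 1.56% and 0.00775% (one-sided permutation p = 0.000999 for each). For the share with both, TEAD4 and JUN were shifted separately, which also broke their overlap with each other. That comparison therefore cannot tell whether TEAD4 and JUN go together at these regions, which is tested below. Of the 24530 regions with JUN, 17.5% (17.0 to 17.9) held YAP, TAZ and TEAD4, and 33.6% (33.0 to 34.2) held any of them. With lists of equal length, JUN was present at 44.8% of the YAP and TAZ regions and the number of 4-factor regions was 2216.

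**Figure D3:**
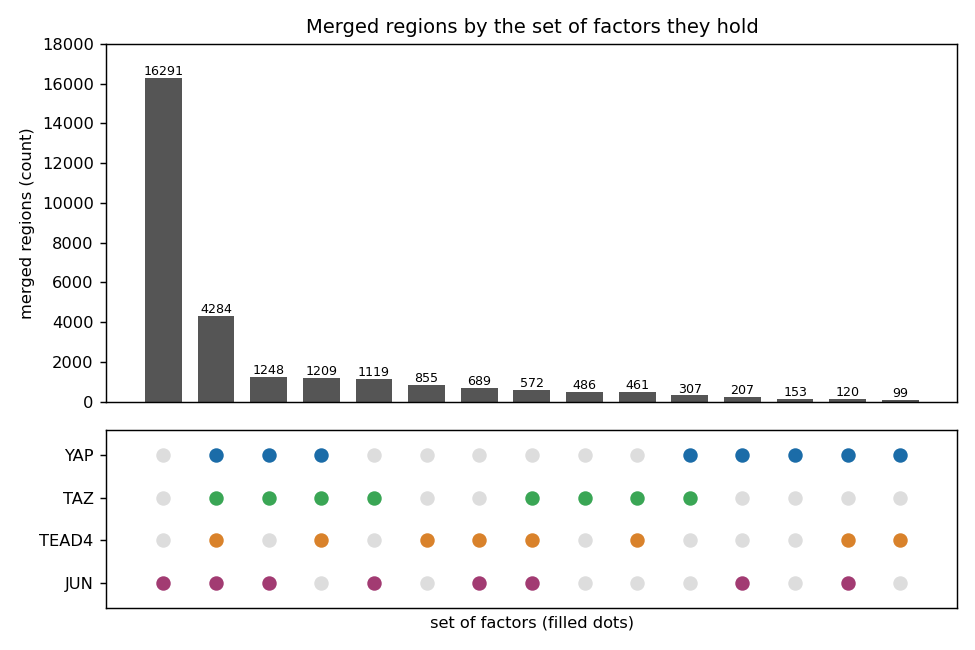
Number of merged regions (bars, with the count above each) for each of the 15 sets of factors, marked by the filled dots under the bar. JUN alone is the largest class with 16291 regions, and the regions with all 4 factors come next with 4284.

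Whether JUN goes with TEAD4 at these sites was tested next. Among the regions with YAP and TAZ, JUN was present at 78.0% of the 5493 with TEAD4 and at 80.3% of the 1555 without it. The odds ratio was 0.872 (95% Woolf interval 0.758 to 1.00), which did not pass the test (two-sided Fisher exact p = 0.0546, adjusted p = 0.0819 over 3 tests). Within 10 parts by YAP and 10 by TAZ enrichment it was 0.745 (Mantel-Haenszel, 0.641 to 0.867), with the interval below 1. Among the regions with YAP or TAZ, the shares were 73.8% and 73.1% (odds ratio 1.03, 0.943 to 1.13, Fisher exact p = 0.48, adjusted p = 0.48). Among regions with TEAD4, JUN was more frequent where both YAP and TAZ were present than at the rest: 78.0% of 5493 against 49.4% of 2796 (odds ratio 3.63, 3.29 to 4.00, Fisher exact p = 2.04e-150, adjusted p = 6.12e-150). The rest comprised 1252 regions with 1 of YAP and TAZ, JUN being present at 55.3% (52.5 to 58.1), and 1544 with neither, JUN being present at 44.6% (42.1 to 47.1). In 3 equal parts of the TEAD4 regions by enrichment, a split made after seeing the data, the odds ratio was 2.84 in the weakest, 3.87 in the middle and 6.30 (4.85 to 8.18) in the strongest part. Of the 277 regions of the strongest part that did not hold both YAP and TAZ, 101 belonged to the 194 TAZ and TEAD4 regions described above. Without that set the odds ratio there was 2.92 (2.14 to 4.00), and 3.18 (2.87 to 3.51) over all TEAD4 regions. The Fisher odds ratio at YAP and TAZ regions fell below 1 past the threshold under 4 alternative settings. Among them, summits within 200 bp and peaks narrowed to 200 bp are nearly the same rule, and another is the lowest of 3 parts by YAP enrichment. Lists of equal length were not run for the Fisher tests. The odds ratio at YAP or TAZ regions passed the threshold in both directions. The latter was 0.766 with the stronger 50% of each list (Fisher exact p = 7.88e-06). It was 1.11 without the 1-Mb bins dense in those 194 regions (Fisher exact p = 0.0324) and 1.15 without the regions themselves (Fisher exact p = 0.00304). All of the 194 held TEAD4 and only 9 held JUN. Leaving them out takes regions mostly without JUN from those with TEAD4 alone, so the rise to 1.15 follows from the selection. All these tests take regions as independent, although regions cluster, so their p-values overstate the precision.

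Where peaks overlapped, their summits lay close together. The median distance was 17 bp between YAP and TAZ (95% interval from resampling chromosomes, 16 to 17; 7122 peak pairs), 16 bp between YAP and TEAD4 (15 to 17; 5752 pairs) and 17 bp between TAZ and TEAD4 (16 to 17; 6568 pairs). Distances to the JUN summit were longer: 27 bp from YAP (26 to 28), 27 bp from TAZ (26 to 28) and 31 bp from TEAD4 (30 to 32). Overlapping peaks of shifted lists had medians between 286 and 372 bp. Summits lay within 100 bp of each other in 97.9% of YAP and TAZ pairs and in 84.9% of TEAD4 and JUN pairs. In the 4129 regions with exactly 1 peak of each list, the YAP summit was nearer to TEAD4 than to JUN in 61.1% (59.6 to 62.6) of those without a tie, and the TAZ summit in 61.0% (59.4 to 62.5).

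**Figure D4:**
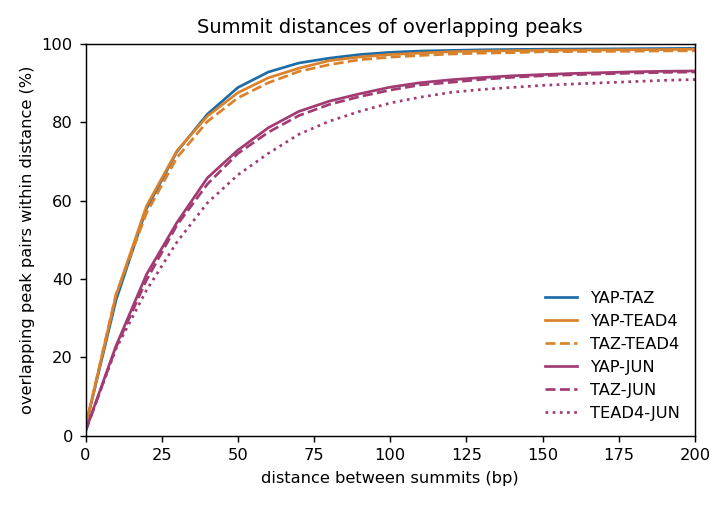
Cumulative share of overlapping peak pairs (y axis, in %) whose summits lie within a given distance (x axis, in bp), 1 line per pair of factors. The 3 pairs among YAP, TAZ and TEAD4 rise together, with medians of 16 to 17 bp, ahead of the 3 pairs with JUN, with medians of 27 to 31 bp.

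Shared peaks were stronger than unshared ones in every list. YAP peaks with TAZ had a median enrichment of 7.54 against 5.85 without (ratio 1.29), and those with TEAD4 8.03 against 6.28 (ratio 1.28). The ratio was smaller for JUN, 7.41 against 7.15 (1.04). TAZ peaks gave ratios of 1.39 with YAP, 1.34 with TEAD4 and 1.06 with JUN, and TEAD4 peaks 1.33 with YAP, 1.33 with TAZ and 1.09 with JUN. JUN peaks were stronger with YAP (1.26), TAZ (1.25) and TEAD4 (1.20). All 12 differences passed a two-sided permutation test of the rank sum with 100000 resamples (adjusted p = 2e-05 for YAP with JUN and 1.09e-05 for the others, from a smallest possible p of 1e-05). Peaks are not independent replicates, so these p-values compare peaks of a list and not samples.

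At shared sites the enrichment of YAP followed that of TAZ closely (Spearman rho 0.87 across sites, 0.86 to 0.88). It followed TEAD4 less closely, with rho 0.60 for YAP (0.58 to 0.61) and 0.59 for TAZ (0.57 to 0.61). The relation to JUN enrichment was weaker, with rho 0.17 for YAP (0.14 to 0.19), 0.20 for TAZ (0.17 to 0.23) and 0.19 for TEAD4 (0.16 to 0.22). Over the same 4129 regions, rho with TEAD4 exceeded rho with JUN by 0.46 for YAP (0.42 to 0.50) and by 0.42 for TAZ (0.39 to 0.45). These differences were computed after the single correlations had been seen. YAP and TAZ libraries share a sequencing run and IgG controls, and share neither with the TEAD4 and JUN libraries.

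The 10 regions with the best mean rank of enrichment over the 4 lists were spread over 8 chromosomes. The first lay on chromosome 14 (100045753 to 100046914), with enrichments of 25.2 for YAP, 27.2 for TAZ, 23.9 for TEAD4 and 29.1 for JUN, and its 4 summits fell within 9 bp. The second lay on chromosome 7 (151451009 to 151452016), with 28.5 for YAP, 22.1 for TEAD4 and 29.3 for JUN, and summits within 71 bp. The third, on chromosome 1 (19335734 to 19338140), had its JUN summit up to 1131 bp from the others. The rest lay on chromosome 1 (16499464 to 16500720), chromosome 15 (63400049 to 63400774), chromosome 22 (39570373 to 39571662), chromosome 11 (69311329 to 69312645), chromosome 2 (28021704 to 28022997 and 227342435 to 227343790) and chromosome 8 (41009053 to 41009855). In these 7 regions the YAP enrichment ranged from 19.1 to 27.3 and the JUN enrichment from 24.0 to 32.7.

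Regions with all 4 factors also occurred in groups. Of the 100-kb windows that held any, 2632 held 1, 537 held 2 and 128 held 3. The window with the most was on chromosome 11 (12000001 to 12100000) with 7, all of the YAP and TAZ regions there, alongside 4 further regions. The next were on chromosome 1 at 172800001 to 172900000 and at 86000001 to 86100000, with 6 each.

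**Figure D5:**
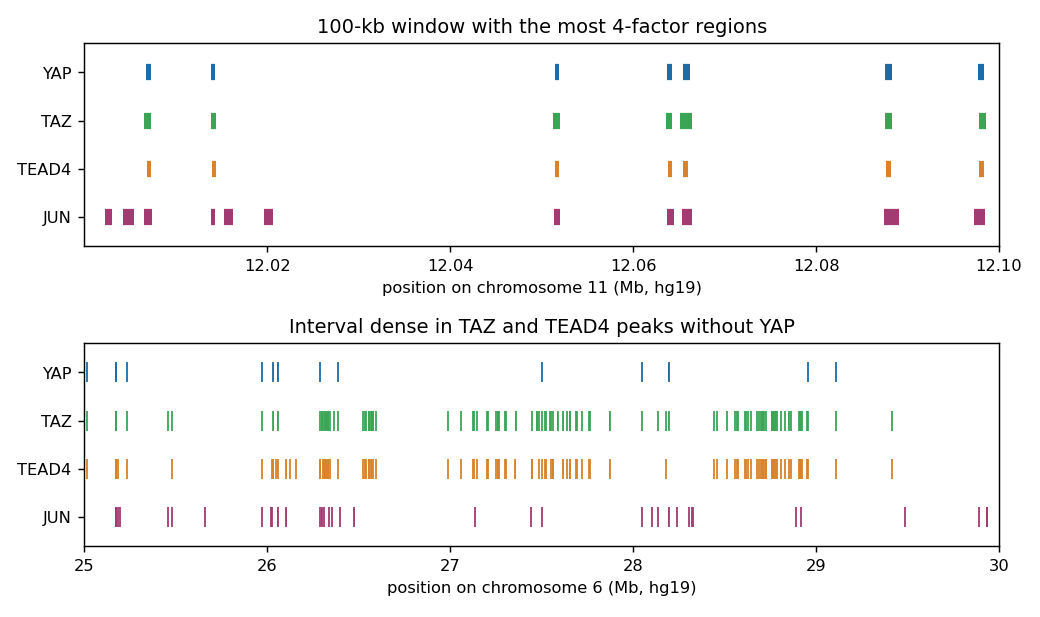
Positions of the listed peaks (bars above, ticks at summits below; x axes in Mb on hg19; 1 row per factor) in the chromosome 11 window with 7 regions of all 4 factors and on chromosome 6 around 26 to 29 Mb. In the upper map each of the 7 YAP peaks stands above TAZ, TEAD4 and JUN peaks; in the lower map the interval from 26 to 29 Mb holds 95 TAZ and 98 TEAD4 peaks against 8 YAP and 24 JUN peaks.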

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

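Across 46 results and 206 alternative values, 168 kept their direction and side of the threshold, stayed within the interval of the reported value or, for counts, within 1.5 times of it. All 108 alternatives of the pairwise overlaps stayed above chance at the smallest p, and the 24 of the strength ratios and 6 of the correlations kept direction and threshold. The rule for overlaps asked only for the side of chance, so it does not show how far a share moved. Of the other alternatives, 13 of 35 for the co-occupied sites, 14 of 21 for the Fisher tests and 3 of 12 for the summit distances were kept. Leaving out the bins dense in strong TAZ and TEAD4 regions without YAP, or those regions, and the 3 parts by TEAD4 enrichment were chosen after seeing the results; the narrowed peaks in the Fisher tests and the test at YAP or TAZ regions were added after the lists were examined but before any test of JUN presence. With local shifts, the chance overlap of the pairwise comparisons was 0.956% to 3.51%. Neither kind of shift takes account of which parts of the genome can be bound. Leaving out a replicate could not be run, since there is 1 list per factor. No paired analysis was possible because the lists hold no values per replicate. Distance to start sites, motifs and gene lists were not run. What depth limits is unknown here.

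Shares of YAP and TAZ regions moved with list length and the overlap rule. With summits within 200 bp, 76.9% held TEAD4, 74.0% JUN and 56.3% both; JUN was at 73.2% of the regions with YAP, TAZ and TEAD4, and 16.2% of JUN regions held those 3. Peaks narrowed to 200 bp gave 76.9%, 74.0%, 56.3%, 73.1% and 16.2%. The stronger 50% of each list gave 3542 YAP and TAZ regions and 1673 of all 4 factors, with shares of 75.2%, 64.1%, 47.2%, 62.8% and 13.6%. Lists of equal length gave 44.8% with JUN, 34.7% with both, 2216 regions of all 4 factors, JUN at 44.3% of those with YAP, TAZ and TEAD4, and these 3 at 28.8% of JUN regions. That setting shortens the TAZ, TEAD4 and JUN lists together. The YAP list keeps all its 7709 peaks, so the fall of JUN at YAP peaks from 77.0% to 41.4% comes from the shorter JUN list. How far each list moves the shares of regions was not tested.

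The odds ratio of JUN by TEAD4 at YAP and TAZ regions, 0.872, passed the threshold at 0.832 with summits within 200 bp (Fisher exact p = 0.00557), 0.790 with the stronger 50% (p = 0.00451), 0.831 with peaks of 200 bp (p = 0.00506) and 0.775 in the lowest of 3 parts by YAP enrichment (p = 0.0163), but not at 0.935 in the middle (p = 0.599) or 0.605 in the highest part (p = 0.103). At YAP or TAZ regions it reversed from 1.03 to 0.766 with the stronger 50% (Fisher exact p = 7.88e-06). It passed the threshold at 1.11 without the dense bins (Fisher exact p = 0.0324). Without the strong TAZ and TEAD4 regions lacking YAP it passed at 1.15 (Fisher exact p = 0.00304). Those 194 regions all held TEAD4 and only 9 held JUN, so the rise to 1.15 follows from leaving them out. Other causes were not tested. Lists of equal length were not run for the Fisher tests. Median summit distances in the stronger 50% were 13 bp (YAP and TAZ), 12 (YAP and TEAD4), 13 (TAZ and TEAD4), 25 (YAP and JUN), 25 (TAZ and JUN) and 29 (TEAD4 and JUN). Among narrow peaks they were 21, 23 and 23 bp for YAP, TAZ and TEAD4 with JUN, against 27, 27 and 31 bp over all pairs. For YAP and TAZ, YAP and TEAD4, and TAZ and TEAD4 they were 16, 17 and 16 bp among narrow peaks.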

Other observations

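The tests on strong TAZ and TEAD4 regions without YAP, the test of TAZ peaks without YAP, the draws matched on JUN enrichment and the rotations along the genome were chosen after the results were seen; the other tests of this part were written down after the lists had been examined but before the results they measure were seen. Regions with all 4 factors lay near each other more often than JUN regions do: 16.2% had another within 10 kb, against a mean of 9.73% and a maximum of 11.5% in 1000 random draws of as many JUN regions, and a maximum of 11.8% in draws matched on JUN enrichment. The share of JUN regions with all 4 factors ran from 12.7% on chromosome 22 to 19.5% on chromosome 10. A permutation fixed in advance gave p = 2.6e-04, but it takes regions as independent, and they cluster. When the marks were rotated along the ordered JUN regions, which keeps the clustering, 0.783 of the 24530 rotations gave as large a chi-square over chromosomes. The observed chi-square was 52.5 and the median of the rotations 61.0. Rotation also keeps broader variation along the genome and only moves it. It therefore cannot separate a difference between chromosomes from such variation, and none is shown or excluded.

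A hypothesis written before any test of JUN presence was run held that JUN is more frequent at YAP and TAZ regions that also hold TEAD4, with peak strength and the width of merged regions as technical explanations. It came out negative. The odds ratio was 0.872 (0.758 to 1.00), on the other side of 1. Within 10 parts by YAP and 10 by TAZ enrichment it was 0.745 (Mantel-Haenszel, 0.641 to 0.867, from 67 of 100 strata with enough regions), and with peaks of 200 bp it was 0.831. With no excess of JUN to explain, these values decide nothing about either explanation, and neither had hidden an excess. At similar YAP and TAZ enrichment, JUN was less frequent at regions with TEAD4, the Mantel-Haenszel interval lying below 1. That interval takes regions as independent.

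Strong TAZ and TEAD4 regions without YAP (194 regions) are the least anticipated pattern here. The TAZ libraries shared their run and IgG libraries with YAP, so neither sets TAZ apart from YAP. TEAD4, from another run and other IgG libraries, lay at 93.3% of the 208 strong TAZ peaks without YAP. This set was chosen without regard to TEAD4, and 1000 local shifts gave at most 10.6%. These values argue against signal confined to the TAZ libraries. Unspecific enrichment in the TAZ and TEAD4 libraries alike would give the same overlap, so the overlap cannot decide on it. Listed JUN peaks lay at 8.17% of these 208 peaks, so most lacked JUN enrichment strong enough to be listed. The share was 69.5% at weaker TAZ peaks without YAP, which need not be the rate that unspecific enrichment would give. Beyond that, the comparison, chosen after the results were seen, decides nothing. Weaker JUN enrichment stays open, since the JUN list starts at a −log10 p of 54.4. Up to 138 JUN peak numbers are unused between the listed JUN peaks that flank the chromosome 6 interval (25971318 to 29484252). The YAP threshold cannot be told apart from a missing YAP signal: 40 regions exceed the unused YAP peak numbers around them, but whether those numbers count every candidate was not measured. Antibody-specific signal, a filter applied to the YAP list alone and binding of TAZ and TEAD4 without YAP stay open and untested. As background, this part of chromosome 6 is known for histone and transfer RNA genes. Whether the peaks there, or those in the dense bins on other chromosomes, lie on such genes was not tested.

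YAP and TAZ summits lay nearer the TEAD4 summit than the JUN summit. Wider JUN peaks are argued against as the whole cause by the 489 regions where the JUN peak was no wider than the TEAD4 peak. There the YAP summit was still nearer TEAD4 in 64.2% (59.7 to 68.5) of regions without a tie. Among narrow peaks, however, the median distance from JUN was 21 bp for YAP and 23 bp for TAZ, against 27 bp for each over all pairs. Part of the difference may therefore go with peak width. Weak JUN peaks with badly placed summits are argued against by 59.9% (57.3 to 62.4) among regions whose JUN peak was in the top 20% of its list. The share was lower where the TEAD4 peak was weaker than the JUN peak by rank within its list. It was 57.0% (54.9 to 59.0) for YAP and 55.7% (53.6 to 57.8) for TAZ, against 61.1% and 61.0% over all regions. The TEAD4 and JUN libraries came partly from different runs, and a difference in fragment length between libraries was not tested. No biological explanation was tested.

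Peaks without a partner differ between the lists in how far a threshold accounts for them. A hypothesis written in advance covered YAP peaks without TAZ and the reverse, but its test read the YAP list only. There the values fit a threshold, with TAZ at 99.9% of the strongest of 10 parts of the YAP list. The reverse test, added later, gave YAP at 82.4% of the strongest part of the TAZ list, which a threshold on TAZ strength does not explain. For JUN, 62.5% of the strongest part held any other factor, which argues against the JUN threshold as the whole cause; the thresholds of the other 3 lists stay open.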
